A study of Homo sapiens with 30 samples.

How the data were processed

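CUT&RUN libraries were made from wild-type and edited neural progenitor cells of the H9 line with a commercial kit and sequenced on an Illumina NextSeq, per the labels' protocols. The submitters' processing notes name BWA 0.7.17, SAMtools 1.9, Picard 2.8.1, bedtools 2.30.0, deepTools 3.5.2 and MACS2 2.2.9.1 with build hg38, without roles or options. The deposited lists are in the broad peak format and carry peak names in the style of MACS2. Each comes from 1 antibody and 1 set, so peaks were taken as called per library and not on pooled libraries; which control was used is not given in the sources used here. The authors' fold value per peak is a ratio of signal over background as the peak caller gave it. The deposited significance value is −log10 of the q-value, and the lowest values lie just above 1, which corresponds to a list limited at q = 0.1. The remaining score columns were not used. The consolidated file holds 3 columns, chromosome, start and end, with no measurement; how the authors consolidated it is not given in the sources used here.

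Of 30 samples, the 4 wild-type RING1 and RNF2 libraries (2 per antibody) are represented by peak lists, and all other libraries were not analysed here. The file names show genotype, antibody and a number shared by 1 RING1 and 1 RNF2 list. The labels tie neither number to a replicate, so the lists were called set A and set B, and they do not say whether the replicates come from separate cultures. The series' design text speaks of RNA sequencing, which was not analysed here. Sequencing depth per library was not given in the sources used here, so a missing peak is not evidence of absence and no counting interval was computed.

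Peaks on chromosomes 1 to 22, X and Y were kept. Overlap meant at least 1 bp in common. Expected overlaps came from 1000 random placements of the peaks of 1 list within their own chromosomes (bedtools 2.31.1 shuffle, fixed seeds), so the smallest possible p is 0.000999. Chromosome lengths were taken from the last annotated gene end, since no genome was at hand. Gene positions were those of RefSeq on GRCh38.p14, the assembly behind hg38, for 20037 protein-coding genes. The first plan used transcription start sites; the annotation gives no strand or transcripts, so windows of 2 kb around both annotated gene ends replaced them in all analyses, and a peak at the far end of a gene or at a neighbouring promoter counts for the gene. All members of the 25 gene lists, also fixed in advance, matched a gene of the annotation. They were tested against all other protein-coding genes with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over 100 tests at 0.05. Such tests take genes as independent, which clustered genes are not, so the calls were also rotated 10000 times along the gene order. Rotation does not account for members that share 1 peak. Widths and fold enrichments of shared and unshared peaks were compared by permutation tests of the difference in medians with 100000 resamples. Merged regions were unions of touching or overlapping peaks of the 4 lists.

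Genes named in the text follow a rule fixed in advance: the 10 genes per antibody with the largest smaller-of-both fold enrichment in sets A and B, the 10 genes with RNF2 in both sets and no RING1, up to 4 members per gene list ranked in the same way by RNF2, RING1 and RNF2 themselves, and the 5 widest peaks of each list. Where several peaks lay at a gene, the highest fold enrichment was used. Some genes that the rule names are not reported here. The PCDHG genes were chosen after their values were seen.

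Other settings fixed before the data were examined were a −log10 q of at least 5, lists cut to the 659 most significant peaks each, chromosomes 1 to 22 only, an overlap of 50% of the shorter peak, merging of peaks within 1 kb, windows of 1 kb and 5 kb, and each set left out in turn. Alternatives chosen after seeing the data were gene bodies extended by 2 kb, rotation of the calls, placement within 10 kb of gene ends, 1 gene per shared gene end, and each peak list left out of the count of lists above other genes in all lists. The alternatives used 100 placements, whose smallest p is 0.0099. Comparisons that need strand or sequence (5′ ends only, a background of CpG-rich promoters) were not run.

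The overlap and gene-list steps were tested on simulated data. A simulated list of 2000 peaks with 50% planted on RNF2 peaks of set A returned 50%. In the simulation over 20037 genes, each gene list was tested against 4 simulated peak lists. All 20 tests of planted gene lists were called, and 1 of 56 tests of gene lists with nothing planted was. Simulated calls were independent between genes, so the simulation does not cover clustered genes or genes that share a peak. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.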

Results

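RING1 and RNF2 are the paralogous ubiquitin ligases at the core of Polycomb repressive complex 1 (PRC1), which places a single ubiquitin on histone H2A (H2AK119ub1) at the chromatin of silenced developmental genes. The series profiled 30 CUT&RUN libraries from neural progenitor cells grown as a monolayer from H9, an established human embryonic stem cell line, across 5 genotypes of an edited RING1 and RNF2 allelic series. CUT&RUN releases the DNA around an antibody-bound protein with a tethered nuclease. The results below concern the wild-type libraries made with antibodies against RING1 and against RNF2, with 2 libraries per antibody, for which 4 peak lists and 1 consolidated region file were analysed. Libraries of the edited genotypes and of H2AK119ub1 and IgG were not analysed here, so no comparison between genotypes was made. The peak lists come in pairs, 1 RING1 list and 1 RNF2 list per pair, called set A and set B here; the labels do not say which set is replicate 1. Read depth was not given in the sources used here, and with 2 lists per antibody no interval across replicates was computed.

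Called RNF2 peaks covered more of the genome than RING1 peaks in both sets, and set A held more peaks than set B for both proteins. On chromosomes 1 to 22, X and Y, RING1 had 12891 peaks over 17.4 Mb in set A and 659 peaks over 1.36 Mb in set B. RNF2 had 16263 peaks over 28.2 Mb in set A and 5901 peaks over 10.7 Mb in set B. Set A thus held 19.6 times as many RING1 peaks and 2.76 times as many RNF2 peaks as set B. Median peak width was 704 bp for RING1 and 973 bp for RNF2 in set A, and 1320 bp and 779 bp in set B. The authors' fold enrichment over background, used to describe and rank peaks within a list and, as the smaller of both sets' values, to choose the genes named, had a median of 3.99 and 4.04 for RING1 and RNF2 in set A and of 4.49 and 3.69 in set B. A −log10 q of at least 5 was reached by 1531 RING1 and 3052 RNF2 peaks of set A, and by 7 RING1 and 472 RNF2 peaks of set B.

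The first question was whether the replicate lists place each protein at the same sites. For RING1, 632 of the 659 set B peaks (95.9%) overlapped a set A peak by at least 1 bp, against a mean of 1.39% over 1000 random placements within the same chromosomes. For RNF2, 4506 of the 5901 set B peaks (76.4%) overlapped a set A peak, against 2.08% at random. Both one-sided p-values were 0.000999, the smallest that 1000 placements can give. Because the lists differ in length, the covered bases shared by both sets were a small part of their union, with a Jaccard index of 0.0777 for RING1 and 0.305 for RNF2.

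The second question was whether the paralogs occupy the same regions, and most RING1 peaks lay at RNF2 peaks. In set A 10578 RING1 peaks (82.1%) overlapped an RNF2 peak of the same set, and in set B 597 did (90.6%); random placement gave 1.89% and 0.761%. The reverse shares were lower, since 61.4% of RNF2 peaks in set A and 5.58% in set B overlapped a RING1 peak. These shares depend on the length of the lists: with each list kept to its 659 most significant peaks, 63.3% of RNF2 peaks overlapped RING1 and 65.7% of RING1 peaks overlapped RNF2 in set A, and 39.9% and 79.5% in set B. Across sets, 96.2% of set B RING1 peaks overlapped a set A RNF2 peak and 31.4% of set A RING1 peaks overlapped a set B RNF2 peak. Every overlap of the full lists had a one-sided permutation p of 0.000999, the smallest that 1000 random placements can give. The lists of a set may have been called against a shared IgG control, which was not analysed here, so part of the overlap within a set may come from shared background.

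Merging all 4 lists gave 19856 regions. RNF2 was present in both sets at 4240 regions, and RING1 was called in at least 1 set in 3833 of them (90.4%). All 3833 had RING1 of set A, and 290 (6.84%) had RING1 of set B. RING1 was present in both sets at 306 regions, all of which also held RNF2. The 290 regions present in all 4 lists had a median width of 16907 bp, against 579 bp for the 5848 regions with RNF2 of set A alone and 341 bp for the 2238 regions with RING1 of set A alone. Part of this contrast follows from the merging, since a union of more peaks is wider and a wider region meets more lists. Both antibodies of set A, with neither of set B, called 6109 regions. A RING1 peak of set A was present at 51.2% of the regions with RNF2 in set A only and at 4.20% of those with RNF2 in set B only (Fisher's exact test, two-sided, odds ratio 23.9, p = 1.37e-298). For RING1 of set B these shares were 0.134% and 0%, so RING1 of set B did not follow RNF2 of its own set there. Regions are not independent replicates, and their width and strength were not held fixed.

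**Figure D1:**
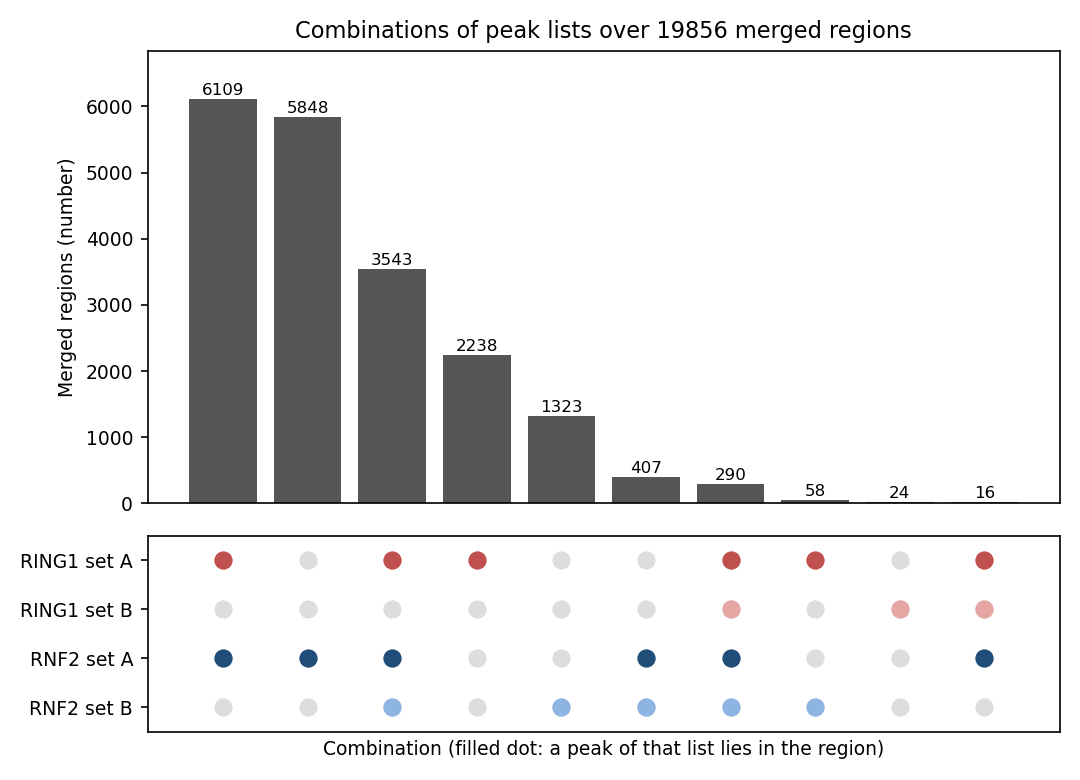
Number of merged regions (bars, vertical axis) for each combination of the 4 wild-type peak lists (filled dots below each bar). The most frequent combinations are both antibodies of set A without set B (6109 regions) and RNF2 of set A alone (5848), and 290 regions carry all 4 peaks.

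Peaks of both proteins lay at gene ends. With no strand in the annotation, a gene was assigned a peak within 2 kb of either annotated end, so starts and ends of genes are pooled. By this measure 63.3% of RING1 and 61.2% of RNF2 peaks in set A, and 49.5% and 61.9% in set B, lay at an end of a protein-coding gene, against 6.39% to 7.27% at random. Another 19.4% to 21.9% of peaks lay in other parts of genes, below the 38.4% to 39.3% at random. The remaining 16.9% to 28.7% lay elsewhere, below the 53.6% to 55.2% at random. Each peak was counted in 1 place only, so the high share at gene ends lowers both other shares. The lower share in other parts of genes is therefore no evidence that peaks avoid them. Each difference had a two-sided p of 0.000999, the smallest possible.

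Among 20037 protein-coding genes, RING1 was at an end of 9144 genes in set A and 264 in set B, with 263 in both. RNF2 was at an end of 11236 genes in set A and 4343 in set B, with 4161 in both, and 257 genes were in all 4 lists. RING1 and RNF2 shared 8620 genes in set A, where independent lists would share 5128 (odds ratio 52.0), and 257 in set B, where independent lists would share 57.2 (Fisher's exact test, two-sided, odds ratio 141, p = 1.64e-161). The counts in both sets rest on set B, the shorter list of each antibody; set A alone gives the larger counts above.

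RING1 peaks present in both sets were ranked by gene. By the smaller of both fold enrichments, the leading 10 genes included PRDM6, OTP, PAX7, IRX5, NKX2-3, TBX20, TCF21, SIM1 and DLX1. PRDM6 on chromosome 5 (123089241 to 123194266, hg38) had a RING1 fold enrichment of 10.8 in set A and 6.18 in set B. OTP, a homeobox gene of hypothalamic neurons, had 14.2 and 6.07, and DLX1, a homeobox gene of forebrain interneurons, had 13.9 and 5.90. For RNF2 the leading genes included SIM1, FOXD1, FOXD3, OSR2, TBX18, CDKN2C and PITX1, with STK3 and LOC112268016, which share the peak of OSR2. SIM1, a transcription factor gene of the hypothalamus on chromosome 6 (100385009 to 100464921), had an RNF2 fold enrichment of 17.5 in set A and 12.8 in set B. CDKN2C, which encodes a cyclin-dependent kinase inhibitor, had 17.8 and 9.71. The genes of the paralogs themselves differed: RING1 (chromosome 6, 33208500 to 33212716) had no peak at its ends in any list, and RNF2 (chromosome 1, 185045558 to 185102603) had a RING1 peak (4.86) and an RNF2 peak (4.51) in set A only.

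Homeobox genes carried both proteins far more often than other genes, as the plot of shares for 25 gene lists fixed in advance shows. All 39 HOX cluster genes had RING1 in set A and RNF2 in both sets, and 22 had RING1 in set B, where 1.21% of other genes did (adjusted exact p = 8.26e-31). Of 120 non-HOX homeobox genes, 112 and 62 had RING1 in sets A and B, and 113 and 104 had RNF2 (adjusted exact p = 3.54e-28, 2.04e-84, 6.80e-20 and 5.78e-51). ISL2, a motor neuron factor gene, had an RNF2 fold enrichment of 18.0 in set A and 9.49 in set B, and POU4F1, a sensory neuron factor gene, had 15.7 and 9.42. Two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 100 tests placed 14 lists above other genes for RING1 in set A, 10 in set B, 15 for RNF2 in set A and 14 in set B; 3, 2, 3 and 3 lists lay below. The 7 lists above other genes in all 4 peak lists were HOX cluster, non-HOX homeobox, T-box, forkhead box, mesoderm, neural crest and neuronal differentiation. Some lists share members, such as TBX20 and TBX18 in mesoderm and T-box and FOXD3 in neural crest and forkhead box, so the 7 are not separate groups. The T-box call for RNF2 in set A ended with windows of 5 kb, with gene bodies extended by 2 kb or when calls were rotated along the genome, and with only 7 RING1 peaks left in set B at a −log10 q of at least 5, 3 lists stayed above other genes there.

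**Figure D2:**
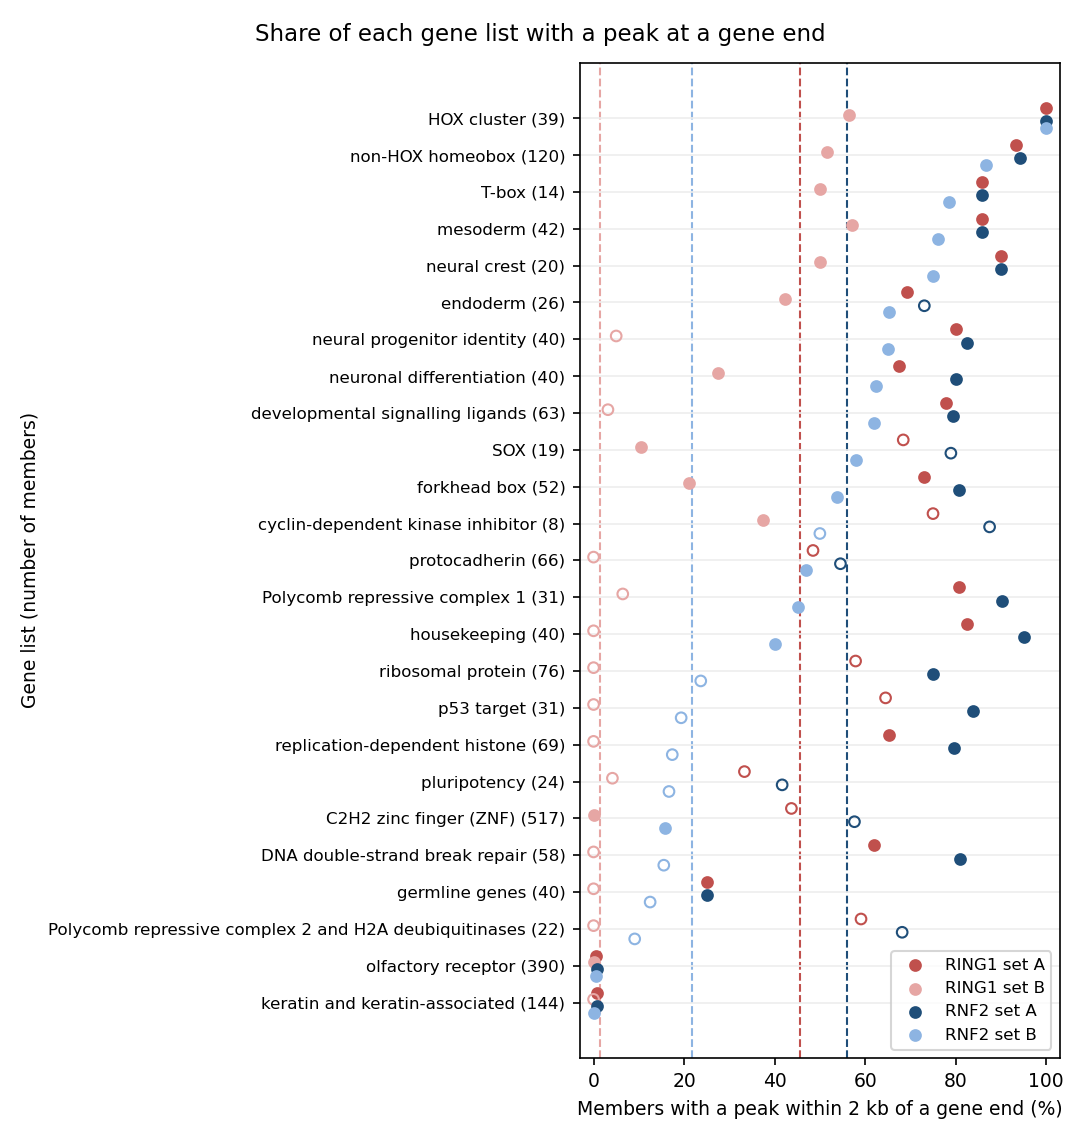
Share of the members of each gene list (vertical axis, number of members in brackets) with a peak within 2 kb of a gene end (horizontal axis, percent), by peak list (colour). Filled points passed the adjusted threshold of 0.05, open points did not, and dashed lines give the share of all protein-coding genes (45.6%, 1.32%, 56.1% and 21.7% for RING1 set A, RING1 set B, RNF2 set A and RNF2 set B); all 39 HOX cluster genes lie at 100% in 3 of the 4 lists.

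Mesoderm, neural crest, forkhead box and T-box genes carried both proteins more often than other genes in both sets. Among 42 mesoderm genes, RING1 was at 36 in set A and 24 in set B and RNF2 at 36 and 32 (adjusted exact p = 5.30e-07, 9.28e-34, 0.000170 and 4.29e-13). TBX20 and TBX18, T-box genes of heart and somite development, had RNF2 fold enrichments of 17.5 and 18.0 in set A and 8.97 and 10.2 in set B. The 26 endoderm genes had RING1 at 18 and 11 and RNF2 at 19 and 17; RNF2 in set A did not pass (adjusted exact p = 0.154), and the RING1 call in set A (adjusted exact p = 0.0287) was lost with windows of 5 kb, while RNF2 in set A passed with lists of equal length (46.2%) and at a −log10 q of at least 5 (53.8%). GATA4 and FOXA1, which specify endoderm derivatives, had RNF2 fold enrichments of 15.6 and 17.3 in set A. Of 20 neural crest genes 18 and 10 had RING1 and 18 and 15 had RNF2. Forkhead box genes had RING1 at 38 and 11 of 52 members and RNF2 at 42 and 28, and T-box genes had RING1 at 12 and 7 of 14 and RNF2 at 12 and 11. As given above, the T-box call for RNF2 in set A was lost with windows of 5 kb, extended gene bodies or rotation. SOX genes had RING1 at 13 and 2 of 19 and RNF2 at 15 and 11, and passed the test in set B (adjusted exact p = 0.0405 and 0.00136) and not in set A (adjusted exact p = 0.0917 for each). With windows of 5 kb the RING1 call of SOX genes in set B was lost and both calls in set A were gained (RING1 78.9%, RNF2 84.2%), as they were at a −log10 q of at least 5 (31.6% and 36.8%).

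Genes of neuronal differentiation and of neural progenitor identity carried RNF2 in both sets. Of 40 neuronal differentiation genes, RING1 was at 27 in set A and 11 in set B and RNF2 at 32 and 25 (adjusted exact p = 0.0115, 1.55e-11, 0.00409 and 1.23e-07). TBR1 and ISL1, factor genes of cortical projection neurons and motor neurons, had RNF2 fold enrichments of 17.2 and 17.3 in set A and 9.18 and 7.69 in set B. The 40 neural progenitor identity genes had RING1 at 32 in set A and 2 in set B (adjusted exact p = 5.08e-05 and 0.135; set B passed with windows of 5 kb, 7.5%) and RNF2 at 33 and 26 (adjusted exact p = 0.00136 and 2.00e-08). PAX6, a neural progenitor factor gene on chromosome 11, had an RNF2 fold enrichment of 11.2 and 7.98, a RING1 fold enrichment of 9.49 in set A and no RING1 peak in set B. PAX3 lay under an RNF2 peak of 66554 bp in set A. Developmental signalling ligands had RING1 at 49 and 2 of 63 and RNF2 at 50 and 39, among them GDF6 (RNF2 10.6 and 6.37) and WNT6 (5.57 and 5.80); their calls in set A ended when each list was kept to its 659 most significant peaks, and those of RING1 in set A (9.52%) and RNF2 in set B (6.35%) at a −log10 q of at least 5. Pluripotency genes did not pass in any list (8, 1, 10 and 4 of 24); PRDM14, a germ cell and pluripotency regulator gene, had RNF2 at 12.9 and 8.42.

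PRC1 genes carried RNF2 in both sets, and RING1 in set A, more often than other genes. RING1 was at 25 and RNF2 at 28 of 31 PRC1 genes in set A (adjusted exact p = 0.000215 and 0.000184), and at 2 and 14 in set B (adjusted exact p = 0.0917 and 0.00635), where RING1 passed with windows of 5 kb (9.68%) or gene bodies extended by 2 kb (12.9%), with BMI1 at RNF2 fold enrichments of 15.7 and 7.10 and CBX8 at 10.5 and 6.39. The RNF2 peak given for BMI1 (22321099 to 22331706) in set B met only 1 end of the gene, running from 22331216 to 22348305. PRC2 and H2A deubiquitinase genes did not pass in any list (RING1 13 and 0, RNF2 15 and 2 of 22). Cyclin-dependent kinase inhibitor genes had RING1 at 6 and 3 of 8 members and RNF2 at 7 and 4, and passed for RING1 in set B (exact test, adjusted p = 0.000280) and in no other list; at a −log10 q of at least 5 the RING1 set B share was 0% and those of RING1 and RNF2 in set A (37.5% and 62.5%) and RNF2 in set B (37.5%) passed. CDKN2A and CDKN2B, neighbouring senescence genes on chromosome 9, lay under 1 RNF2 peak of set A with a fold enrichment of 14.7.

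DNA double-strand break repair, the process named in the series title, and genes of general cell function carried RNF2 in set A more often than other genes. Of 58 repair genes RING1 was at 36 and RNF2 at 47 in set A (adjusted exact p = 0.0274 and 0.000215), and at 0 and 9 in set B (adjusted exact p = 1 and 0.402). NHEJ1, an end-joining factor gene, had an RNF2 fold enrichment of 8.12 and 5.84 and PRKDC, the gene of the DNA-dependent protein kinase, had 4.59 and 4.39. Housekeeping genes had RING1 at 33 and 0 and RNF2 at 38 and 16 of 40 (RNF2, adjusted exact p = 2.28e-07 and 0.0185), with ALDOA at RNF2 8.06 and 5.90. RNF2 in set A was at 57 of 76 ribosomal protein genes, 26 of 31 p53 target genes and 55 of 69 replication-dependent histone genes (adjusted exact p = 0.00151, 0.00325 and 0.000136), whereas set B had 18, 6 and 12, none past the test. RING1 was at 44, 20 and 45 of these members in set A (adjusted exact p = 0.0574, 0.0693 and 0.00292) and at 0 in set B; the RING1 set A call of ribosomal protein genes was gained with windows of 1 kb (56.6%) or 5 kb (63.2%) and with 1 gene per shared gene end (58.7%), and that of p53 targets with windows of 5 kb (71.0%). When each list was kept to its 659 most significant peaks, every call of these 5 groups ended, and RNF2 of set A was at 3.45% of repair genes and 0% of p53 targets. The histone calls also ended when calls were rotated along the genome.

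Olfactory receptor and keratin genes carried few peaks. Olfactory receptor genes had RING1 at 2 and 0 and RNF2 at 3 and 2 of 390 (adjusted exact p = 7.11e-99, 0.0190, 7.57e-133 and 2.23e-37), the 1 list below other genes in all 4 peak lists. Keratin and keratin-associated genes had RING1 at 1 and 0 and RNF2 at 1 and 0 of 144. Germline genes had RING1 and RNF2 at 10 of 40 in set A (adjusted exact p = 0.0180 and 0.000213) and at 0 and 5 in set B, not past the test; the set A calls ended at the stricter q and in lists of equal length. C2H2 zinc finger genes lay below other genes in set B (RING1 1 and RNF2 82 of 517, adjusted exact p = 0.0274 and 0.00194), calls that ended when calls were rotated along the genome or at a −log10 q of at least 5, as did the RING1 set B call of olfactory receptors; in set A they did not pass (RING1 226, 43.7% against 45.7%, and RNF2 298, 57.6% against 56.0%; adjusted exact p = 0.465 and 0.544), though RING1 in set A was below other genes past the threshold with lists of equal length (1.55%) and at a −log10 q of at least 5 (5.03%). Protocadherin genes had RNF2 at 31 of 66 in set B (adjusted exact p = 1.96e-05), through only 10 distinct peaks: 22 PCDHG genes share 1 annotated end and so 1 peak, and counting genes of a shared end once left 10 of 31 members (adjusted exact p = 0.243). The span of the PCDHG genes held 0 RNF2 peaks of set B and 0 RING1 peaks of set A. The RNF2 peak of set B counted for these 22 genes thus lay outside them and may belong to a neighbouring gene. RING1 was at 32 and 0 and RNF2 in set A at 36 protocadherin genes, not past the test; RING1 in set A passed with gene bodies extended by 2 kb (68.2%) and RNF2 in set A at a −log10 q of at least 5 (39.4%).

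The 4 HOX clusters were covered almost end to end in all lists but RING1 of set B. The HOXB span ran from HOXB1 to HOXB9 and left out HOXB13, so the HOXB shares do not cover that gene. A single RNF2 peak of set A covered 100% of each cluster, the widest being 149946 bp over HOXC on chromosome 12 (53913811 to 54063756). RNF2 of set B covered 98.5% of HOXA, 84.6% of HOXB, 89.7% of HOXC and 87.5% of HOXD, and RING1 of set A covered 98.1%, 82.9%, 92.7% and 92.1%. RING1 of set B left most of each cluster uncovered, with 15 peaks over 19.4% of HOXA and 15 over 21.2% of HOXD, 4 over 5.69% of HOXB and 9 over 3.69% of HOXC. Outside the clusters, the 5 widest peaks per list included GATA4 for RING1 in set A (48529 bp), SHOX2 with RSRC1 for RING1 in set B (16384 bp) and ZIC2 with ZIC5 for RNF2 in set B (42424 bp).

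**Figure D3:**
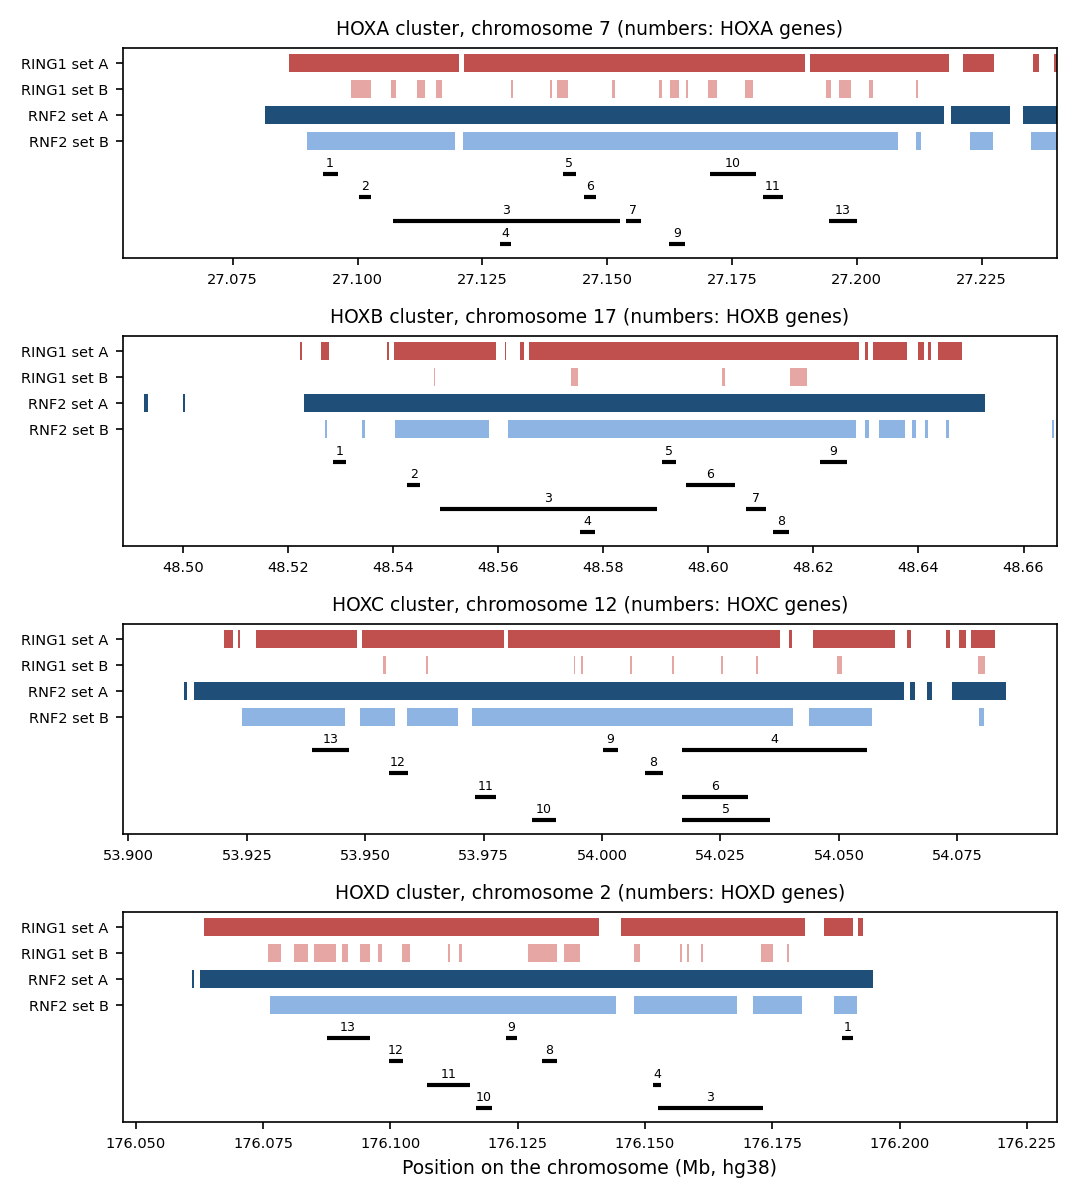
Peaks of the 4 lists (coloured bars) and annotated HOX genes (black lines with gene numbers) along each HOX cluster (horizontal axis, position in Mb, hg38). RNF2 of set A spans each cluster with 1 peak, and RING1 of set B covers between 3.69% and 21.2% of a cluster in separate short peaks. HOXB13 lies outside the HOXB span used.

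Genes with RNF2 in both sets mostly had RING1 as well: 3828 of 4161 (92.0%) had a RING1 peak in at least 1 set, and 333 did not. Within set B, 257 of the 4343 genes with RNF2 had RING1. The share of 92.0% thus rests almost wholly on RING1 of set A, which was at 45.6% of all protein-coding genes. All 104 non-HOX homeobox genes with RNF2 in both sets had RING1 in at least 1, against 91.8% of the other genes with RNF2 (Fisher's exact test, adjusted p = 0.00757), the only 1 of 24 lists past the test. The 39 HOX cluster genes and the 39 developmental signalling ligands with RNF2 also all had RING1 but did not pass (adjusted exact p = 0.566 for each). The strongest RNF2 genes without RING1 were RHOU, PFN3, NLGN1, GRIPAP1, STON2, ALOX12, CREG2, TMEM108, KCNH1 and DNAJC3. The RNF2 peaks of PFN3 and ALOX12 lay within 2 kb of the gene but outside it in both sets, so they may belong to a neighbouring gene. NLGN1, which encodes a synaptic adhesion protein, had an RNF2 fold enrichment of 4.50 in set A and 4.70 in set B. Ranked by RNF2 fold enrichment in set A into 5 equal groups of 848 merged regions, regions with RNF2 in both sets lacked RING1 in 30.9% of the weakest group and in 0 of the strongest. That count of 0 allows a share of up to 0.354% if regions are taken as independent. A missing RING1 peak can be a missed call, and no gene had RING1 in both sets without RNF2. With 1 set at a time the number of lists past the test of RING1 with RNF2 against RNF2 alone was 6 for set A and 9 for set B. At a −log10 q of at least 5 it was 0, so the non-HOX homeobox call ended there.

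**Figure D4:**
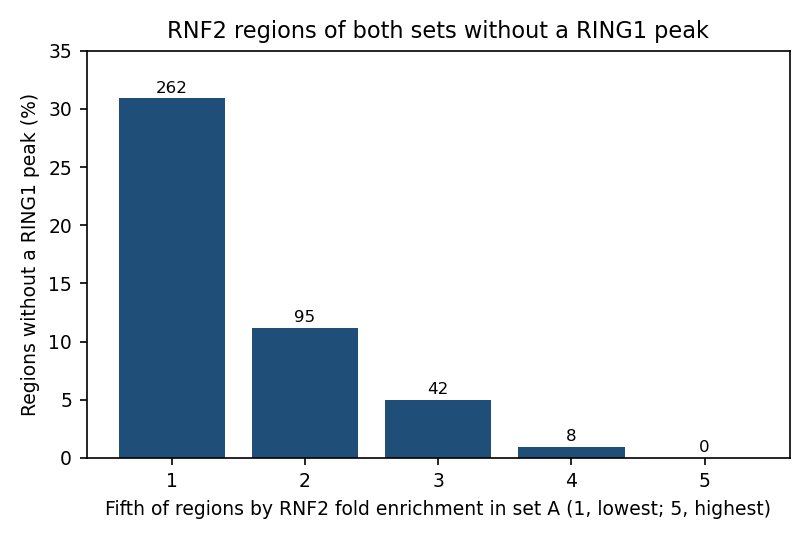
Share of merged regions with RNF2 in both sets that lack a RING1 peak (vertical axis, percent), in 5 equal groups by RNF2 fold enrichment in set A (horizontal axis, 1 weakest to 5 strongest); numbers above bars count regions without RING1. The share is 30.9% in the weakest group (262 of 848) and 0.943% in group 4.

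Peaks shared by both proteins were wider and stronger than the others of their list. In set A the median width of RING1 peaks was 816 bp where RNF2 overlapped and 342 bp elsewhere, and that of RNF2 peaks was 1303 bp with RING1 and 594 bp without. Median fold enrichment was 4.14 against 3.56 for RING1 and 4.49 against 3.58 for RNF2. In set B the 329 RNF2 peaks with RING1 had a median width of 9634 bp and fold enrichment of 5.92, against 741 bp and 3.66 for the other 5572. Each of these had a permutation p of 1e-05, the smallest that 100000 resamples can give. RING1 peaks of set B had 1449 bp against 526.5 bp (permutation p = 0.00122) and 4.52 against 4.30 (permutation p = 0.00721). Wider peaks meet another list more easily by chance, and peaks are not independent replicates.

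The consolidated file held 4255 regions with a median width of 2100 bp and 79.7% at a gene end. All of them overlapped an RNF2 peak of set A, 99.6% an RNF2 peak of set B, 90.5% a RING1 peak of set A and 7.19% a RING1 peak of set B. These shares follow from how the file is built out of the same lists and are no independent evidence. The file matched a simple rule: of the 4256 merged regions in which RNF2 was called in both sets or RING1 was called in both sets, 4255 were in the file with the same end and a start 1 bp lower, and 0 regions of the file fell outside the rule. RNF2 in both sets supplied 4240 of the 4256 regions, and the other 16 had RING1 in both sets without RNF2 in both.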

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

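The ratio of RNF2 list lengths and the comparison among genes with both antibodies in set A were chosen as tests only after the results were seen. RING1 and RNF2 of set A held peaks outside the chromosomes used in the comparisons, above the limit of 3 that a count of 0 allows. RING1 of set A had 12 peaks on the mitochondrial genome and on unplaced or alternate sequences, of which 3 were mitochondrial. RNF2 of set A had 7 on unplaced or alternate sequences.

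The first pattern is the short RING1 list of set B, 659 peaks against 12891. A candidate explanation is lower signal over background in set B, so that only the strongest sites were called: the set A peaks also called in set B had a median percentile of 98.2 (bootstrap SE 0.163) for fold enrichment within the set A list, where at least 75 had been set in advance as the bound. These were 321 peaks, and the value shows that they were strong in set A, not why the list was short. Lower read depth, which was not given, would give the same value. A fault of the RING1 reaction alone would leave the RNF2 lists of similar length, and the RNF2 list was also shorter in set B, by 2.76 times. This is 1 ratio between 2 libraries, with no spread and chosen as a test after it was seen, so it does not decide the question. The RING1 lists differ by 19.6 times, so a further shortfall specific to RING1 stays open. No biological explanation was tested, since both sets carry the same genotype.

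The second pattern is the 407 regions with RNF2 in both sets and no RING1 peak. Sites that differ in RING1 whatever their RNF2 strength were tested by splitting regions into 5 equal groups by RNF2 fold enrichment. The share without RING1 in the strongest group divided by the share over all was 0, from 0 of 848 regions. That count allows a share of up to 0.354% if regions are taken as independent. Such sites would not give this fall, but region width was not held fixed. Median width was 1282 bp without RING1 and 2094 bp with RING1 of set A only. A wider region meets a RING1 peak more easily, so the split does not separate RNF2 strength from width. Missed RING1 calls at sites weak for both proteins may account for the pattern, since the median RNF2 percentile of the regions without RING1 minus that of the regions with RING1 was −40.9 (bootstrap SE 1.47). The share without RING1 was 30.9% in the weakest group, 11.2% and 4.95% in the next, and 0.943% in group 4. Weak sites that truly hold RNF2 alone would give the same values, and the design names no group that separates them.

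The third pattern is regions called in 1 set only. For the 6109 regions with both antibodies of set A and none of set B, weaker sites that only set A reaches would have needed a median RNF2 percentile at least 20 below that of regions with RNF2 in both sets; the difference was −19.4 (bootstrap SE 0.747), which neither meets that bound nor rules it out. Background at open promoters of active genes stays open: housekeeping and ribosomal protein genes carried such calls more often than all other genes (37.9% against 23.8%, odds ratio 1.96, Fisher's exact p = 0.000662) but not past the threshold among genes with both antibodies in set A (57.1% against 55.5%, odds ratio 1.07, exact p = 0.818), and the IgG libraries were not analysed here. For the 1381 regions with RNF2 in set B only, chance calls placed without regard to genes are argued against as the whole cause, since 16.9% lay at a gene end and the highest of the random placements was 7.97%, though the share was 79.8% for RNF2 in both sets. No biological explanation was tested for either part.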

How the results depend on the processing

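The rotation of calls, gene bodies extended by 2 kb, 1 gene per shared gene end, placement within 10 kb of gene ends and the omission of single peak lists were alternatives chosen after seeing the data. Of 245 values other than single gene lists under an alternative, 224 kept their direction and side of the threshold, or stayed within 1.5 times for counts. All tests of overlap, location, shared genes and shared against unshared peaks did so under each alternative run, while their sizes moved. The tests of the consolidated regions are counted here too, although the file is built from the same lists and they are no independent evidence. The share of RING1 peaks at RNF2 peaks, averaged over both sets (86.3%), ranged from 72.6% to 90.6%, and that of RING1 and RNF2 set B peaks in set A from 80.3% to 100% and from 59.5% to 92.2%. The share of RNF2 peaks at RING1 peaks ranged from 41.7% to 63.3% in set A and from 1.27% to 39.9% in set B, genes shared by both proteins from 505 to 9525 and from 5 to 313, and the difference in median width between shared and unshared peaks of set A from 474 bp to 5640.5 bp for RING1 and from 709 bp to 7389 bp for RNF2. The shares of consolidated regions at a peak fell as low as 12.4% (RING1 set A), 0.165% (RING1 set B), 13.9% (RNF2 set A) and 10.3% (RNF2 set B).

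Counts moved by construction where peaks were removed. At a −log10 q of at least 5 the lists kept 1531 (RING1 set A), 7 (RING1 set B), 3052 (RNF2 set A) and 472 (RNF2 set B) peaks, 5 genes had RING1 and 483 had RNF2 in both sets, 3 gene lists lay above other genes for RING1 in set B and 0 below, 1 lay below for RNF2 in set B, 3 lay above in all peak lists, and 0 passed the test of RING1 with RNF2 against RNF2 alone. Lists of equal length held 659 peaks and left 441 genes with RNF2 in both sets. Rotation left 0 lists below other genes for RING1 in set B. With 1 set left out in turn (leave-one-out), genes with RING1 numbered 264 to 9144, genes with RNF2 4343 to 11236, and gene lists past the test of RING1 with RNF2 against RNF2 alone 6 to 9. With each peak list left out in turn, 7 to 11 gene lists lay above other genes in all the others, the highest without RING1 of set B.

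Among 800 values of single gene lists, 721 stayed, 37 lost and 26 gained the threshold, and 16 reversed. Reversed means that a call past the threshold changed direction, whether or not the opposite direction passed. A share of 0% where few peaks remain is therefore a lost call and not evidence of depletion. With 7 RING1 peaks left in set B at a −log10 q of at least 5, the shares of HOX cluster, SOX, cyclin-dependent kinase inhibitor, endoderm, forkhead box, neural crest and neuronal differentiation genes were 0%; other reversals there were housekeeping (RNF2 set B, 2.5%), protocadherin (RNF2 set B, 0%) and replication-dependent histone genes (RING1 set A, 2.90%). With lists of equal length, DNA double-strand break repair (RNF2 set A, 3.45%), p53 target (RNF2 set A, 0%), developmental signalling ligands (RING1 set A, 1.59%), protocadherin (RNF2 set B, 1.52%) and replication-dependent histone genes (RING1 set A, 0%; RNF2 set A, 0%) had a lower share than other genes; the cause was not tested.

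No paired analysis was possible because the labels tie the numbers of the lists to no replicate and the overlaps come from no fit that can hold a replicate block; RING1 and RNF2 lists that share a number were compared within their set. Placement near start sites was run with gene ends, and 5′ ends alone and a CpG-rich background were not run for want of strand and sequence. Shared and unshared RING1 peaks of set B could not be compared at the stricter threshold, nor RNF2 peaks of set B, for want of peaks. Depth is unknown, so a missing peak in set B cannot be read as absence.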

Other observations

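These tests of single gene lists between sets were added after seeing the data. Several developmental gene groups were called again in set B more often than other genes called in set A. Peak strength in set A was not held fixed. The RING1 peaks of set A also called in set B had a median percentile of 98.2 for fold enrichment in set A. The tests therefore do not separate the gene group from the strength of its peaks. For RNF2, all 39 HOX cluster genes, 104 of 113 non-HOX homeobox genes (92.0%), 32 of 36 mesoderm genes (88.9%) and 17 of 19 endoderm genes (89.5%) recurred, where about 37% of other genes did (36.8%, 36.5%, 36.9% and 36.9% in turn; Fisher's exact test, adjusted p = 1.34e-16, 1.59e-33, 8.12e-10 and 1.03e-05 over both antibodies and 25 lists). Neural progenitor identity genes (26 of 33, 78.8%), developmental signalling ligands (39 of 50, 78%) and SOX genes (11 of 15, 73.3%) also recurred more often for RNF2 (adjusted exact p = 4.94e-06, 2.66e-08 and 0.0129). For RING1, 24 of 36 mesoderm genes (66.7%) recurred against 2.62% of other genes (adjusted exact p = 5.51e-28), but neural progenitor identity genes (6.25% against 2.86%) and developmental signalling ligands (4.08% against 2.87%) did not pass (adjusted exact p = 0.366 and 0.836), nor did SOX genes (15.4% against 2.86%). Pluripotency genes passed for neither antibody (RING1 12.5% against 2.87%, RNF2 40% against 37.0%; adjusted exact p = 0.336 and 1). DNA double-strand break repair genes recurred less often for RNF2, at 9 of 47 (19.1%) against 37.1% (adjusted exact p = 0.0215), as did C2H2 zinc finger genes, at 78 of 298 (26.2%) against 37.3% (adjusted exact p = 0.000211), and replication-dependent histone genes, at 12 of 55 (21.8%) against 37.1% (adjusted exact p = 0.0483). Housekeeping genes recurred at 16 of 38 (42.1%), not past the test (adjusted exact p = 0.723). These tests take genes as independent, although the 39 HOX cluster genes lie at 5 RNF2 peaks of set A and the 55 histone genes at 36. When the set B calls were rotated along the order of the genes called in set A, the histone call ended (adjusted permutation p = 0.220) and the other calls named here stayed. Rotation does not account for members that share 1 peak. The RNF2 call of protocadherin genes (31 of 36) stayed too (adjusted permutation p = 0.000278), although 22 PCDHG genes share 1 annotated end. A call that stayed under rotation, such as that of HOX cluster genes, may therefore still rest on few peaks.

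The 1 merged region that met the rule of the consolidated file and was not in it spans 880314 to 881778 on chromosome 1 and is the first of the 4256 regions by position.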
